A study of Rattus norvegicus with 22 samples.

How the data were processed

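RNA from 22 samples of Wistar rats was measured on single-colour expression arrays, 1 array per sample. Per the labels' protocols, total RNA was isolated with RNeasy columns, reverse transcribed with an oligo dT primer carrying a T7 promoter and transcribed in vitro into biotin-labelled cRNA. The deposited values are log2 probe set values from RMA (robust multi-array averaging), per the submitters' processing notes. The RMA version, whether all arrays were processed together, and whether RNA was pooled are not given in the sources used here. The table has 15923 rows, of which 57 are array controls, and the 15866 other probe sets were tested without a filter.

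The values ran from 4.86 to 15.22, and the array medians from 8.09 to 8.22. The array SDs ran from 1.51 to 1.83, so the values do not share 1 distribution over the arrays. The number of arrays limits the precision. Gene symbols came from the probe table of the files. Of the probe sets, 12783 had 1 symbol, 312 had several and 2771 had none, which left 10411 distinct genes. An Entrez identifier of 12748 of these probe sets was found in the reference gene table (assembly GRCr8), which served for names and synonyms only. No genome build is named in the labels, and no coordinates are given.

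Samples were grouped by tissue and gestational day into 5 strata: whole embryo at day 12, maternal liver at days 12 and 20, and embryo liver and embryo bone at day 20. Each stratum held 1 control array, 1 array at each EMD 82571 dose (EMD50 and EMD150, for 50 and 150 mg/kg/day) and 1 retinoic acid array, with a further retinoic acid array in both day 12 strata. The codes RA5 and RA56 of the retinoic acid samples are not explained in the sources used here. Whether samples share a dam or litter is not stated either, so the strata were the only repeats of a treatment at day 20.

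Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend). Tests were two-sided and limma's p-values were adjusted by the Benjamini-Hochberg method over all probe sets of a comparison, with a call at an adjusted p under 0.05. There were 22 such comparisons. The first model used all arrays with the stratum as a block and the treatment as a factor, and left 14 residual degrees of freedom. Further models let the treatment effect differ between maternal liver and conceptus (whole embryo, embryo liver and embryo bone together) or between days, each with 11 residual degrees of freedom. A model of the 9 maternal liver arrays with the treatment as a block compared the days, with 4 degrees of freedom. A model of the 10 arrays of day 12 estimated the effects in each tissue of that day, with 2. Its spread comes from the retinoic acid pairs alone, and the control and EMD 82571 arrays, 1 each per tissue, are assumed to vary like them. Without 1 array of a pair, the spread is that of the pair of the other tissue alone. In the models by side, by day and by tissue of day 12, the EMD 82571 effect is the mean of both doses. An effect in a stratum of day 20 has no replicate check and got no p-value.

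Lists of genes were fixed with the design: 36 lists of 1139 genes, of which 817 were measured, 48 through a synonym, and 35 lists with at least 5 measured genes were tested. Each was represented by 1 probe set per gene. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. For genes of a called list, limma's p-values were also adjusted over that list alone. The list was picked in the same data, so a pass there is no separate test of its genes. Within a stratum, a list's median difference was placed among those of 10000 random lists of the same size, matched on mean level in 10 bins, as a description of those arrays. A percentile below 2.5 or above 97.5 marked a list as shifted, and the text gives only some of the lists so marked.

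The named genes were chosen by a rule. In comparisons over several strata these are up to 15 genes per direction with the largest fold change among the called ones, or, with fewer than 5 called, the 5 with the smallest p per direction. In a stratum they are up to 12 per direction by the smaller of the differences of both doses or both retinoic acid arrays, when at least 2-fold. Up to 4 genes of each called list were added, as were Cyp26a1, Rarb, Dhrs3 and Cyp26b1 for retinoic acid and Alb, Afp, Col1a1, Col2a1 and Hbb as checks of the labels. The genes printed are those of them that a reader needs, and a gene outside the rule is said to be so.

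The scripts were tested on simulated data in which 500 changed probe sets of each size were spread over 5 draws. Changes of 1 and 2 log2 units were recovered in 96% and 99.8% of cases for EMD150 against control over all strata, and in 96.4% and 99.8% for retinoic acid. The recovery was 93% and 99.8% for EMD 82571 in the conceptus, and 87.6% and 99% in maternal liver. For retinoic acid in maternal liver of day 12 alone it was 16% and 88.4%.

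The alternatives were quantile normalisation over all arrays, subtraction of each array's median, a filter on low values, eBayes without the trend, the mean of the retinoic acid pairs, 1 probe set per gene, the mean of a gene's probe sets for the lists, only the arrays of the groups compared, other fold thresholds within a stratum, and leaving out each array or stratum in turn. Further alternatives were eBayes with its robust option, and treatment and day as a random block. The test, these alternatives, the lists and the rule for naming genes were set before the data were examined. Others were added later: quantile normalisation within each stratum, arrays scaled to the same SD, the difference of the GAPDH 3' and 5' probe sets as a covariate, and fits without arrays that carry genes of another tissue or signs of degraded RNA.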

Results

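The data were the RNA levels of 22 samples taken from pregnant Wistar rats and their offspring. Dams had received vehicle, retinoic acid at 12 mg/kg/day or a drug at 50 or 150 mg/kg/day, named EMD 82571 in the series title and MSC1096199 in its design text. The drug belongs to the calcium sensitisers, which raise the response of muscle to calcium, and retinoic acid is a form of vitamin A known to cause malformations. The protocols give dosing on gestational days 6 to 11 and 6 to 17, and the series text gives days 6 to 17 only. Samples were whole embryo at day 12, maternal liver at days 12 and 20, and embryo liver and embryo bone at day 20. Each of these 5 strata held 1 control, 1 EMD50, 1 EMD150 and 1 retinoic acid array, and both day 12 strata a second retinoic acid array (RA5 and RA56).

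The tissue labels were checked with marker genes. Alb, the gene of serum albumin, lay between 15.13 and 15.22 in the maternal livers and between 14.94 and 14.98 in the embryo livers. Afp, its fetal counterpart, lay between 14.63 and 14.67 in embryo liver and between 8.08 and 9.28 in maternal liver. The collagen genes of bone and cartilage were high in embryo bone, with Col1a1 at 14.55 to 14.68 and Col2a1 at 12.31 to 13.43. Arrays of a stratum correlated across probe sets with r between 0.954 and 0.996 (38 pairs), and arrays of different strata with r between 0.688 and 0.985 (193 pairs). The pair of retinoic acid arrays had r = 0.980 in whole embryo and 0.996 in maternal liver. Probe sets are not independent replicates.

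EMD150 was compared with control over all strata to find genes that the high dose shifted alike in every tissue. As a group, genes of calcium handling, the channels, pumps and binding proteins that move calcium in cells, were higher, in 29 of 40 genes (camera, adjusted p = 0.0222, and adjusted p = 0.7 with an estimated correlation). Genes that detoxify drugs under the receptors CAR and PXR were also higher, in 22 of 29 genes (0.0181, and 0.7 with an estimated correlation). Lower were the fatty acid oxidation genes driven by PPAR-alpha, in 26 of 34 (0.0283), and the genes of gluconeogenesis and amino acid breakdown, in 19 of 25 (0.0222), each with an adjusted p = 0.7 with an estimated correlation. Nervous system genes were higher in 32 of 42 (0.0198, and 0.723 with an estimated correlation) and pancreatic acinar genes lower in 17 of 21 (0.0222, and 0.832 with an estimated correlation). None of the 6 lists was called by fry, with adjusted p from 0.181 to 0.538. In every stratum the EMD150 array had a smaller SD of values than the control, such as 1.675 against 1.832 in whole embryo. The lists were not tested again on rescaled values, so a part of array spread in them stays open.

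The calcium genes with the smallest p were the channel genes Cacna1d, at 0.30 ± 0.083 (log2 difference ± SE), and Trpv5, at 0.45 ± 0.14. Pln, which encodes the brake of the calcium pump of the sarcoplasmic reticulum, differed by 0.31 ± 0.087 and the pump gene Atp2b2 by 0.33 ± 0.10. Their adjusted p was 0.195 over all probe sets. Adjusted over the list alone, which was picked in the same data, these 4 genes passed. The first 3 were higher in 5 of 5 strata and Atp2b2 in 4 of 5. The other probe set of Pln was lower, at -0.10. Other probe sets were nearer 0 for Trpv5 (0.091), Atp2b2 (0.045) and Cacna1d (0.021 and 0.18). Among the lower metabolic genes were Got1 at -0.62 ± 0.17, Asl at -0.46 ± 0.14, Fbp1 at -0.60 ± 0.20 and Agxt at -0.45 ± 0.15, of enzymes that handle amino acids and make glucose, which passed when adjusted over the list alone. Ech1, of fatty acid oxidation, did so too, at -0.77 ± 0.21. Phox2a at 0.37 ± 0.11 and Sox10 at 0.28 ± 0.089 led the nervous system genes, and Abcc3 at 0.47 ± 0.16 and Ugt2b1 at 0.52 ± 0.19 the detoxification genes.

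No gene was called by limma in this comparison, and 2925 of 15866 probe sets had an unadjusted p under 0.05. The smallest adjusted p was 0.195, shared by Nr0b1 at 0.31 ± 0.062, Sult1e1 at 0.22 ± 0.047, Syt7 at 0.49 ± 0.10 and Erbb4 at 0.45 ± 0.10, and on the lower side by Ap3d1 at -0.47 ± 0.094, Dhrs4 at -0.45 ± 0.093, Tmem131 at -0.53 ± 0.11 and Pnisr at -0.61 ± 0.13. Without the EMD150 maternal liver of day 12 only the nervous system list was called, and without the maternal liver control of day 20 there were 3. The calcium list was not called without the whole embryo control either (adjusted p up to 0.141), and the nervous system list not without the EMD150 bone (0.261). The PPAR-alpha list was not called without the control or EMD150 array of any of the liver strata (up to 0.253). The gluconeogenesis list was lost without the control of bone or of either maternal liver (up to 0.122), and the acinar list without the latter (up to 0.653).

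At the low dose, EMD50 against control, 10 lists were called, none of them with an estimated correlation (adjusted p from 0.707 to 0.729) or by fry (0.878). The yolk sac and trophoblast genes were lower, in 24 of 32 genes (adjusted p = 0.0022), with the fetal serum protein genes Afp at -1.17 ± 0.54, Apoa1 at -0.96 ± 0.48 and Fgg at -0.98 ± 0.51. In bone these genes differed by -4.52, -2.46 and -3.31 from a control in which liver genes were high, so bone weighs much in these means. The hepatocyte list (20 of 26), which shares Afp and Apoa1 with the yolk sac list, and the acinar list (16 of 21), the adipocyte list (14 of 14) and the PPAR-alpha list (23 of 34) were also lower, each at an adjusted p of 0.0141. So were gluconeogenesis (16 of 25, 0.0268), hypoxia and glycolysis (17 of 30, 0.0259) and keratinocyte genes (14 of 21, 0.0246). Cartilage genes (16 of 19, 0.0259) and clock genes (12 of 16, 0.0495) were higher. No gene was called by limma, with 253 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 1. The smallest p belonged to Slc41a2 at 0.39 ± 0.093, and to the matrix gene Col1a2 at -0.45 ± 0.14 and Fbn1 at -0.31 ± 0.10. The EMD50 bone array has a GAPDH 3' to 5' difference of 2.72, against 0.568 to 0.859 in the other arrays, and without it the cartilage, hepatocyte, gluconeogenesis, PPAR-alpha and hypoxia lists were not called (adjusted p up to 0.635). Without the EMD50 whole embryo 2 lists were called, and without the maternal liver control of day 12 also 2, cartilage and yolk sac, while the acinar list was not called and turned to higher. The yolk sac list was lost only without that EMD50 embryo (0.07). Other arrays that ended a call were the controls of bone (cartilage, gluconeogenesis, hepatocyte), whole embryo (cartilage, clock, keratinocyte), embryo liver (PPAR-alpha, gluconeogenesis, keratinocyte) and maternal liver of day 20 (gluconeogenesis, hypoxia, acinar). So did the EMD50 livers of day 20, maternal (clock, acinar, adipocyte) and embryonic (acinar, keratinocyte), and for the clock list alone (up to 0.81) the EMD150 and retinoic acid arrays of bone and embryo liver and both retinoic acid embryos.

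The direct comparison of the doses asks whether effects grew with dose. EMD150 exceeded EMD50 for the nerve receptor genes Glra2 (0.27 ± 0.067) and Chrm1 (0.25 ± 0.065), for Neurl1 (0.40 ± 0.10) and for the phosphodiesterase gene Pde5a (0.34 ± 0.086). It was below EMD50 for the peptidase gene Lap3 (-0.61 ± 0.15) and the vesicle transport genes Bet1 (-0.61 ± 0.14) and Ap3d1 (-0.41 ± 0.094). The other probe sets of Glra2 (-0.022) and Ap3d1 (0.01) lay near 0. None of the genes named here passed, at an adjusted p of 0.288. Limma called no probe set, and 2311 had an unadjusted p under 0.05.

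Retinoic acid was compared with control over all strata. Among the called genes, Hnrnpa3, a splicing factor gene, rose by 0.93 ± 0.19 (adjusted p = 0.0258), Fxr1 by 1.02 ± 0.23 (0.0328), the primase gene Prim1 by 0.98 ± 0.20 (0.0259), Cdc42 by 0.93 ± 0.19 (0.0258) and Rab10 by 0.90 ± 0.18 (0.0258). The iron regulator Ireb2 rose by 1.16 ± 0.24 (0.0259), Arrdc3 by 1.18 ± 0.23 (0.0253) and the unnamed gene LOC100912041 by 1.48 ± 0.29 (0.0253). Lower were Pja2 at -0.61 ± 0.14 (0.0352), whose other probe set was higher at 0.30, Abcd3, of peroxisomes, at -0.60 ± 0.14 (0.0393), and Yeats2 at -0.43 ± 0.11 (0.0454). Limma called 291 probe sets, 282 higher and 9 lower, for 219 genes, of which 14 probe sets differed by 2-fold or more. Most of the genes named here moved the same way in 5 of 5 strata, with Rab10 and Abcd3 in 4 of 5. The other probe set of Rab10 was higher by only 0.171.

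The count of 291 rested on single arrays. It was 0 without the control or the retinoic acid array of bone, of embryo liver or of maternal liver at day 20, and 0 without the whole embryo control. It was 1 without the RA56 whole embryo, and 437 without the EMD50 bone or without the RA56 maternal liver of day 12. In 3 retinoic acid arrays genes of another tissue were high: muscle genes in the maternal liver of day 20, and adult liver genes in bone and in the RA56 whole embryo, where 0.642 of the liver genes tested were higher (0.585 in RA5, which was kept, and 0.345 in RA56 with the limits used at first). Without these arrays limma called 0 probe sets and 1197 had an unadjusted p under 0.05.

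Lipid synthesis genes were higher in this comparison, and acinar, nervous system and liver genes had the smallest p among the 8 lists called. None of these lists was called with an estimated correlation (adjusted p of 0.812 and 0.817) or by fry. Genes of fatty acid synthesis were higher in 19 of 22 (adjusted p = 0.00251), with Lpin1 up by 0.49 ± 0.12 (0.0413) and Scd at 0.58 ± 0.17 (0.0908), and this list remained called without any 1 array. For cholesterol synthesis (13 of 19, 0.0176), Nsdhl rose by 0.67 ± 0.15 (0.0317) and Idi1 by 0.79 ± 0.20 (0.0488). These lists held 1 and 2 genes called over all probe sets, and 2 and 4 adjusted over the list alone. Acute phase genes (20 of 27, 0.00258) included Cp at 0.77 ± 0.19 (0.0416) and Crp at 0.81 ± 0.21 (0.0497), 2 called over all probe sets and 5 adjusted over the list alone. Hepatocyte genes (20 of 26, 0.00151) and the liver genes that depend on sex and pregnancy (17 of 28, 0.0143) were higher, each with 0 genes called over all and 3 adjusted over the list alone. Muscle genes were higher (36 of 46, 0.00879), Myh1 by 0.76 ± 0.14 (0.0253), with 0.082 to 0.745 at its 4 other probe sets. Nervous system genes were lower (35 of 42, 0.000546), as were acinar genes (19 of 21, 5.91e-06), 12 of them adjusted over the list alone, where 1 was higher. The acinar list, too, was called without any 1 array. Without the whole embryo control 5 lists were called, the acute phase (0.216), hepatocyte (0.136) and sex-dependent (up to 0.451) lists not among them, and the last was also lost without the RA5 embryo. Without the retinoic acid bone 5 were called, and the nervous system (0.173), cholesterol and muscle lists were not. The muscle list was lost without the maternal liver control of day 20 too, and turned to lower without the retinoic acid array of that stratum. The cholesterol list (up to 0.137) was lost without the RA56 embryo, the maternal liver control of day 12, or the control or retinoic acid embryo liver.

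Genes of retinoid metabolism and retinoic acid response are the known direct targets of the treatment. Cyp26a1, which encodes the enzyme that breaks retinoic acid down, differed by 0.92 ± 0.52 (adjusted p = 0.526) over all strata. Rarb (0.079 ± 0.092, 0.824), Dhrs3 (0.075 ± 0.10, 0.852) and Cyp26b1 (-0.018 ± 0.072, 0.956) lay near 0. The lists of retinoid metabolism and of retinoic acid receptors and targets were called in none of the 7 comparisons tested with lists. The same holds for the Hox, limb and craniofacial, cardiac, osteoclast, aryl hydrocarbon receptor, myeloid, p53, heat shock and endothelial lists.

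EMD150 and retinoic acid arrays were compared directly to ask whether the drugs left different profiles. Genes lower in EMD150 than in retinoic acid included the transcription factor gene Maf, which fell by 1.25 ± 0.16 (adjusted p = 0.00147), the RNA-processing genes Lsm5 (-1.08 ± 0.17, 0.00396) and Lsm8 (-1.03 ± 0.20, 0.0073), Gas5 (-1.12 ± 0.18, 0.00487), Tob1 (-1.11 ± 0.24, 0.0114) and Ggnbp2 (-1.04 ± 0.15, 0.00396). Arrdc3 (-1.12 ± 0.23, 0.0091), Fxr1 (-1.23 ± 0.23, 0.0072) and Ube2v2 (-1.29 ± 0.21, 0.00463) are also among the genes higher in retinoic acid than in control. Xist, the RNA that coats the inactive X chromosome, had the largest difference at -2.29 ± 0.58 (0.0195). Its level was 6.00 and 6.64 in EMD150 bone and embryo liver against 11.71 and 11.41 with retinoic acid, and the sex of the embryos, and whether bone and liver share embryos and so are no independent repeats, is not given in the sources used here. Genes higher in EMD150 were Trpv5, an epithelial calcium channel (0.62 ± 0.13, 0.00913), Slc18a2, a vesicular monoamine transporter (0.60 ± 0.11, 0.00718), the neuronal genes Map6 (0.52 ± 0.12, 0.0121) and Cplx1 (0.51 ± 0.14, 0.025), and Abcg5, a sterol transporter (0.66 ± 0.17, 0.0221). Other probe sets gave smaller differences for Maf (-0.452 and -0.082), Trpv5 (0.168), Slc18a2 (0.133), Map6 (0.172 and 0.176) and Cplx1 (0.24).

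Limma called 2282 probe sets between these groups, 1030 higher and 1252 lower in EMD150, for 1626 genes, and 34 differed by 2-fold or more. The count was 481 without the EMD150 bone and 948 without the retinoic acid bone, 754 and 571 without those of embryo liver, and 1206 and 1195 without those of maternal liver at day 20. It was 4156 without the RA5 whole embryo and 1270 without the RA56 whole embryo. Without a whole stratum it was 5 for embryo liver, 237 for maternal liver of day 20, 551 for bone and 1421 for maternal liver of day 12. Without the 3 retinoic acid arrays that carry genes of another tissue it was 2. Both drugs were set against the same controls. Their fold changes correlated across probe sets with r = 0.122, where unchanged treatments gave 0.535 on average (0.499 to 0.558, 100 simulations). The covariance was 0.00418 against a simulated 0.00877, a difference of -0.00459. Over disjoint strata the median r was -0.106 (-0.243 to 0.202, 20 splits). No call was shared, as EMD150 had none.

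The liver clears most drugs, and the response of maternal liver to EMD 82571 was estimated over both days and doses. Detoxification genes under CAR and PXR were higher in 24 of 29 (adjusted p = 9.52e-12, and adjusted p = 0.0226 with an estimated correlation). They were led by the glucuronyl transferase gene Ugt2b1 at 0.83 ± 0.22, by Cyp3a23-3a1 at 0.71 ± 0.23, which encodes the main drug-oxidising enzyme, by Ces2c at 0.42 ± 0.15 and by Gsta3 at 0.998 ± 0.41. Ugt2b1 was the 1 gene higher when adjusted over the list alone. Genes of fatty acid synthesis were higher in 16 of 22 (2.54e-06, and 0.0313 with an estimated correlation), with Scd2 at 1.19 ± 0.38 and Me1 at 0.41 ± 0.18. Cholesterol synthesis was higher in 18 of 19 (5.58e-06, and 0.376 with an estimated correlation), with Acat2 at 0.49 ± 0.23 and Dhcr7 at 0.29 ± 0.16. Bile acid genes (17 of 23, 0.00257, and 0.559 with an estimated correlation) and Nrf2 genes of oxidative stress (13 of 19, 0.00644, and 0.165 with an estimated correlation) were higher, with Slco1a4 at 0.61 ± 0.27 and Nqo1 at 0.33 ± 0.17.

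Lower in these livers were genes of gluconeogenesis and amino acid breakdown, in 18 of 25 (adjusted p = 0.000877, and 0.148 with an estimated correlation), such as Sds at -1.34 ± 0.40. Lower too were PPAR-alpha genes, in 25 of 34 (0.00264, and 0.45 with an estimated correlation), such as Acot1 at -1.05 ± 0.34, and immediate early genes of cAMP signalling, in 28 of 38 (0.0387, and 0.273 with an estimated correlation). Acinar genes of pancreas were lower in 19 of 21 (2.24e-66, and 0.00586 with an estimated correlation), with Amy2a3 at -3.35 ± 0.67, Cela2a at -2.05 ± 0.37 and Pnlip at -1.74 ± 0.29, and 16 genes were lower when adjusted over the list alone. Adipocyte genes were lower in 13 of 14 (8.26e-10, and 0.0226 with an estimated correlation), with Fabp4 at -1.69 ± 0.38 the 1 gene lower when adjusted over the list alone. Acinar genes were high in the control of each day and in the EMD50 liver of day 12, where Amy2a3 lay at 10.35, and Fabp4 was highest in the day 12 control, at 8.24. The adipocyte list was not called without the day 12 control. Fry called none of the 10 lists (0.0946 for the acinar list).

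Limma called no gene for EMD 82571 in maternal liver, with 123 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.0616. The genes with the smallest p were Prss2 and Pnlip on the lower side (0.1) and Ubd at 0.94 ± 0.20 on the higher side (0.336). The count was 6 without the day 12 control, 9 without the EMD50 array of day 12, 3, 4 and 5 without the control, EMD150 and retinoic acid arrays of day 20. The detoxification, cholesterol and acinar lists were called without any 1 array, fatty acid synthesis was not called without the day 20 control (0.323), and the other 6 lists were lost without the day 12 control, where 6 lists were called in all. The Nrf2 list was also lost without the EMD50 array of day 20 or EMD150 of day 12 (up to 0.362), the PPAR-alpha list without EMD150 of day 20 or EMD50 of day 12 (0.198), the bile acid list without EMD50 of day 12 (0.156) and gluconeogenesis without EMD150 of day 12 (0.076). The cAMP list ended without any of these EMD 82571 arrays but EMD150 of day 20, or without the EMD150 embryo liver (up to 0.846). In the day 12 livers alone the control and each dose are 1 array, and the spread comes only from the retinoic acid pairs. On that assumption limma called 11 probe sets for EMD 82571, 1 higher and 10 lower, which a control array that stands apart would also give. They included Amy2a3 (-3.53 ± 0.11, 0.000164), with -1.04 and -6.03 at the doses, Fabp4 (-2.57 ± 0.12, 0.00116) and the brown fat gene Ucp1 (-1.59 ± 0.13, 0.0204). This count was 21 without either retinoic acid liver, and 56 and 55 without the RA5 and RA56 embryo.

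Pancreatic enzyme genes were lower and lipogenic genes higher in maternal liver after retinoic acid. All 12 probe sets called by limma were lower acinar genes. Amy2a3, the amylase gene, fell by 4.86 ± 0.71 (adjusted p = 0.00849), and the log2 difference was -3.47 ± 0.52 (0.00889) for Prss1, -3.27 ± 0.48 (0.00849) for Ctrb1, -2.96 ± 0.40 (0.00749) for Cela2a, -2.41 ± 0.31 (0.00749) for Pnlip and -2.18 ± 0.30 (0.00749) for Clps. These genes were high in the controls of both days and in the EMD50 liver of day 12. The acinar list was lower in 19 of 21 (2.44e-53, 0.0144 with an estimated correlation and 0.00719 by fry), with 16 genes adjusted over the list alone, and it was called without any 1 array. Genes of fatty acid synthesis were higher in 19 of 22 (6.85e-07, and 0.0434 with an estimated correlation), also without any 1 array. Pnpla3 at 0.91 ± 0.24, Scd at 0.89 ± 0.27 and Lpin1 at 0.58 ± 0.19 passed when adjusted over the list alone (0.0389, 0.0472 and 0.0472), and none over all probe sets.

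Red cell genes were lower in 22 of 26 (adjusted p = 0.000287, and 0.593 with an estimated correlation), with Alas2 at -0.92 ± 0.46. Proliferation genes (25 of 36, 0.0183, and 0.891 with an estimated correlation) and adipocyte genes (11 of 14, 0.00176, and 0.449 with an estimated correlation) were lower as well. These 3 lists were not called without the day 12 control (up to 0.726), where 3 lists were called, nor proliferation without RA5 and adipocyte without RA56. Cholesterol synthesis was higher in 14 of 19 (0.0405, and 0.891 with an estimated correlation), and not called without the day 12 control, RA56, the day 20 retinoic acid array or the EMD50 bone (up to 0.631), nor with the mean of a gene's probe sets (0.102). Muscle genes were higher in 36 of 46 (1.65e-07, and 0.821 with an estimated correlation). They were not called without the control of day 20 (up to 0.122), and turned to lower without the retinoic acid array of that day, where 11 lists were called. Cyp26a1 was higher by 2.02 ± 0.77 and did not pass (adjusted p = 1). The count of 12 was 4 without the day 12 control, 0 without the RA5 array, 22 without the day 20 control and 19 without the day 20 retinoic acid array. At day 12 alone the control is 1 array without a replicate, and the spread is that of the retinoic acid pairs. Limma called 19 probe sets there, all lower, which a control that stands apart would also give, with Amy2a3 at -6.00 ± 0.11 (4.42e-06), Ctrb1 at -4.00 ± 0.17 (0.000672) and Fabp4 at -2.32 ± 0.12 (0.000837), and Cyp26a1 was higher by 3.55 ± 0.55 without passing (0.285). That count was 54 without either retinoic acid embryo and 35 without the RA56 liver.

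**Figure D1:**
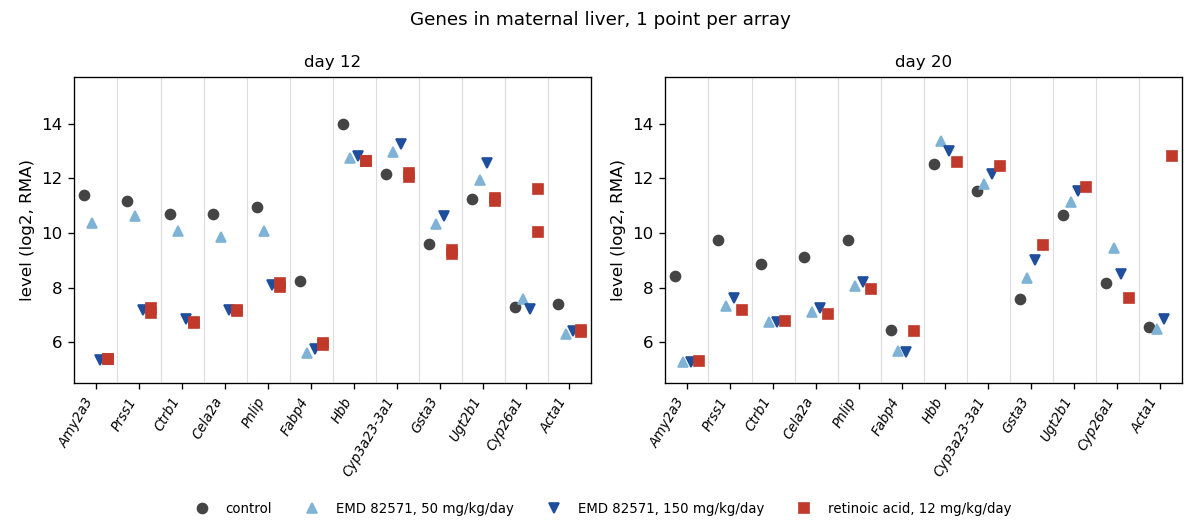
Levels of 12 genes (log2, RMA) in the maternal livers of day 12 and day 20, 1 point per array. The acinar genes Amy2a3, Prss1, Ctrb1, Cela2a and Pnlip are highest in the control of each day, Amy2a3 at 11.39 at day 12 (10.35 at EMD50) and 8.42 at day 20, and Acta1 stands apart in the retinoic acid array of day 20.

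Pregnancy itself changes the liver between these days, and the 9 maternal livers were compared by day with the treatment as a block. No list was tested here, and the genes named are those with the largest changes. The iron hormone gene Hamp fell by 3.38 ± 0.28 (adjusted p = 0.001), as did Cyp3a18 (-2.17 ± 0.18, 0.001) and Cyp2a1 (-1.43 ± 0.24, 0.0152), which encode drug-oxidising enzymes. Lower too were Gpt at -1.62 ± 0.18 (0.0034), Prodh at -1.39 ± 0.15 (0.0034) and Kmo at -1.27 ± 0.17 (0.00709), of enzymes that break down amino acids, and the lipogenic Me1 at -1.24 ± 0.14 (0.0034). Cpt1a, of fat oxidation, rose at day 20 by 1.44 ± 0.15 (0.00335) and the fasting hormone gene Fgf21 by 1.42 ± 0.25 (0.0181), as did Apoa1 by 1.49 ± 0.13 (0.001). A2m, a protease inhibitor gene of pregnancy, rose by 4.01 ± 0.61 (0.0103) and Ccn3 by 3.28 ± 0.14 (7.76e-05). Nr0b2 rose by 1.31 ± 0.29 (0.0354), and was lower at day 20 with the GAPDH difference as a covariate, at -0.30. The GAPDH difference lay at 0.70 to 0.80 in the day 12 livers and at 0.59 to 0.68 in the day 20 livers. As it separates the days by itself, a fit with it cannot tell day from RNA integrity. Limma called 965 probe sets, 390 higher and 575 lower, 92 of them by 2-fold or more, and 20 with that covariate. The count was 183, 427, 385 and 598 without the control, EMD50, EMD150 and RA56 array of day 12, and 185, 427, 381 and 1650 without the control, EMD50, EMD150 and retinoic acid array of day 20.

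In the conceptus, EMD 82571 was estimated over whole embryo, embryo liver and embryo bone. Of the lists 3 were called, each with an adjusted p of 0.725 with an estimated correlation, and none by fry. Cartilage genes were higher in 13 of 19 (adjusted p = 0.0192), among them Col9a2 at 0.62 ± 0.19, Cnmd at 0.53 ± 0.18 and the aggrecan gene Acan at 0.34 ± 0.14. Calcium handling genes were higher in 27 of 40 (0.0419), with Trpv5 at 0.45 ± 0.15 (0.12 at its other probe set) and Trpv6 at 0.32 ± 0.13. The calcium list was not called with the mean of a gene's probe sets (0.0748). Hepatocyte genes were lower in 22 of 26 (0.0143), with Afp at -2.01 ± 0.60, Apoa1 at -1.65 ± 0.45, Plg at -0.95 ± 0.24 and F2 at -0.64 ± 0.19, and these 4 passed when adjusted over the list alone. The contractile gene Tpm2 (-0.73 ± 0.15), the matrix gene Fbn1 (-0.48 ± 0.11) and S100b (0.51 ± 0.11) had the smallest p, at an adjusted p of 0.451. Limma called no gene, and 1733 probe sets had an unadjusted p under 0.05. The hepatocyte and cartilage lists were not called without the bone control, in which liver genes were high, or without the EMD50 bone (up to 0.424), nor the cartilage list without the EMD150 embryo liver. The calcium list was not called without the control, EMD50, EMD150 or RA5 embryo or without the EMD50 or EMD150 embryo liver (up to 0.759). The number of lists was 1 without the EMD50 bone, 8 without the EMD150 bone, 5 without the whole embryo control or the retinoic acid maternal liver of day 20, and 7 without the embryo liver control. Limma called 1 probe set without the EMD50 embryo liver.

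In the conceptus, acute phase and liver secretory genes were higher and neuronal genes lower after retinoic acid. The acute phase genes Cp, Crp and Orm1 rose by 1.12 ± 0.22 (adjusted p = 0.019), 1.16 ± 0.24 (0.0234) and 1.10 ± 0.24 (0.0319), and the list was higher in 19 of 27 (0.000645, and 0.457 with an estimated correlation). Hepatocyte genes were higher in 21 of 26 (0.000223, and 0.457 with an estimated correlation), with Apoh at 1.34 ± 0.31 (0.0389) and Cyp2e1 at 0.71 ± 0.15 (0.0305). The liver genes that depend on sex and pregnancy were higher in 21 of 28 (0.00399, and 0.457 with an estimated correlation), with Cyp2c12 at 1.43 ± 0.33 (0.0366). The acute phase, hepatocyte and sex-dependent genes are high in maternal liver, and other genes of that tissue were higher in the retinoic acid bone and in both retinoic acid embryos (0.642 of those tested in RA56, or 0.345 with the limits used at first, and 0.585 in RA5). Microtubule gene Map2 fell by 0.71 ± 0.15 (0.024), and nervous system genes were lower in 34 of 42 (0.000223, and 0.836 with an estimated correlation).

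Bone matrix genes were also higher, in 20 of 27 (adjusted p = 0.0102, and 0.836 with an estimated correlation), with the periosteum gene Postn up by 0.99 ± 0.21 (0.0259). Hypoxia and glycolysis genes were higher in 22 of 30 (0.0164, and 0.836 with an estimated correlation). Beyond the lists, LOC100912041 rose by 2.23 ± 0.24 (0.000586), Arrdc3 by 1.49 ± 0.24 (0.00924), and the replication genes Prim1 and Rfc4 by 1.37 ± 0.22 (0.00924) and 1.28 ± 0.22 (0.0114), each in 3 of 3 strata. The histone methyltransferase gene Nsd2 fell by 0.99 ± 0.17 (0.0102). Cyp26a1 did not pass, at 0.13 ± 0.65 (0.98). Limma called 302 probe sets, 287 higher and 15 lower, and 78 by 2-fold or more. Adjusted over the list alone there were 5 acute phase, 3 hepatocyte, 5 sex-dependent, 2 bone matrix and 1 hypoxia gene higher and 2 nervous system genes lower, beside 3, 3, 1, 1, 0 and 1 over all probe sets. The count of 302 was 5 and 154 without the control and the retinoic acid array of bone, 96 and 167 without those of embryo liver, and 23 and 102 without the control and RA56 of whole embryo. It was 201 without the EMD150 maternal liver of either day or the RA5 maternal liver, and 42 without the 3 arrays with genes of another tissue. The acute phase, hepatocyte and sex-dependent lists were not called without the whole embryo control (up to 0.522), where 3 lists were called, nor the nervous system list without the retinoic acid bone (0.353). The sex-dependent list was also lost without RA5, the bone matrix list without the whole embryo control, RA5 or the retinoic acid bone (up to 0.262), and the hypoxia list without RA5 or the embryo liver control (up to 0.363).

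Differences between conceptus and maternal liver were tested directly. Limma called none for EMD 82571 (340 probe sets at an unadjusted p under 0.05, smallest adjusted p 0.713) and none for retinoic acid (465, and 0.156). For EMD 82571 the fat gene Fabp4 had the smallest p, with an effect 2.51 ± 0.49 higher in the conceptus. The EMD 82571 count was 3, 8 and 2 without the day 12 control, the day 12 EMD50 and the day 20 control of maternal liver. The retinoic acid count was 2 without the day 12 control, 7 without the EMD50 array of either day, 6 and 14 without the control and retinoic acid array of day 20, all of maternal liver, and 2 without the retinoic acid embryo liver.

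The effects were also estimated by day. No list was tested by day. At day 20 the fatty acid transporter gene Cd36 rose with retinoic acid by 1.504 ± 0.18 (adjusted p = 0.00272), the mitochondrial genes Dld by 1.45 ± 0.21 (0.00878) and Ndufs1 by 1.34 ± 0.28 (0.0219), and Hnrnpa3 by 1.49 ± 0.19 (0.00306). Abcd3 fell by 0.78 ± 0.20 (0.0465). Limma called 424 probe sets, 403 higher and 21 lower, 113 by 2-fold or more. The count was 4 and 96 without the control and retinoic acid bone, 202 and 95 without those of embryo liver, 1 and 97 without those of maternal liver, 654 without the EMD50 bone, and 20 without the 3 arrays with genes of another tissue. At day 12 limma called none (705 probe sets at an unadjusted p under 0.05), with the globin gene Hbb at -1.19 ± 0.21 and the smallest adjusted p (0.469), and Cyp26a1 at 1.80 ± 0.67 (0.923). That count was 5 without the whole embryo control, 1 without the RA56 embryo and 25 without the maternal liver control of day 12. The difference between the days had no call (1183, smallest adjusted p 0.634), with 1 without the retinoic acid embryo liver and 4 without the maternal liver control of day 12. EMD 82571 had no call at day 12 (981, and Hbb at -1.13 ± 0.21 with 0.615), at day 20 (677, and Got1 at -0.70 ± 0.18 with 0.977) or between the days (492, and 0.995). Without the whole embryo control limma called 1 at day 12 and 1 between the days, and without the maternal liver control of day 12 it called 24 and 10.

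Whole embryos of day 12 were compared array by array, since only retinoic acid was repeated. Both EMD 82571 doses had much lower levels than the 1 control of genes of the visceral yolk sac. This membrane feeds the embryo and secretes serum proteins, and whether the samples held unlike amounts of it was not tested. Rbp4, the retinol carrier, lay at 11.25 in the control and differed by -2.67 (EMD50) and -3.49 (EMD150), Apoa1 by -2.17 and -3.22, Apoa4 by -2.16 and -2.45 and the gap junction gene Gjb2 by -2.47 and -2.59. The keratin genes Krt8 and Krt18 and the protease genes Lgmn and Ctsl were among the other genes lower. The yolk sac list had a median of -0.33 (percentile 0). Calcium handling had a median of 0.26 (percentile 100), with Trpv6 at 0.75 and 0.81 and Casq1 at 1.11 and 0.93, but the calcium-binding gene S100g at -1.37 and -1.39. Some of these genes differed alike from the 1 control in the RA5 and RA56 embryos, Gjb2 by -1.04 and -1.71, Casq1 by 1.23 and 0.34 and Trpv6 by 0.63 and 0.29, and the control has the widest spread of values (SD 1.83). Col1a1 was lower by 1.03 at both doses. Of 73 and 139 probe sets that differed by 2-fold or more at the low and high dose, 63 did so at both, 57 lower and 6 higher, and the doses differed from each other in 4. With 1 array per group, limma took the spread from the retinoic acid pairs, and on that assumption called none for EMD 82571 (1679 at an unadjusted p under 0.05, and 0.0971 for the placental hormone gene Prl7a3 at -0.998 ± 0.081). Calls appeared without the RA5 or RA56 embryo, where the spread comes from the maternal liver pair alone, and without either retinoic acid maternal liver.

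Retinoic acid whole embryos had higher LOC100912041 (2.14 and 2.60 in RA5 and RA56), Apoh (2.32 and 1.71), Orm1 (1.65 and 1.61), Alb (1.61 and 3.42) and C3 (1.48 and 3.14). Alb and C3 were also above the 1 control in the EMD50 and EMD150 embryos, by 0.94 and 1.31 and by 0.90 and 1.30. Hepatocyte genes had a median of 0.44 (percentile 100), and adult liver genes beyond this list were higher in these arrays as well. Patterning genes of limb and face moved both ways, with a median of -0.10 (percentile 1.14). The forelimb gene Tbx5 was higher by 0.81 and 0.89, while Prrx1, of limb mesenchyme, differed by -0.75 and -0.76. Proliferation genes had a median of -0.31 (percentile 0.03). Nsd2 differed by -1.76 and -1.55 and the ephrin gene Efnb1 by -1.73 and -1.13 (-1.60 and -1.42 at EMD50 and EMD150). Cyp26a1 was flat, at 0.05 and 0.08. RA5 and RA56 differed from control by 2-fold in 505 and 216 probe sets, from each other in 201, and from control in both in 62. Limma called 5 probe sets, all lower, with Prl7a3 at -0.96 ± 0.081 (adjusted p = 0.0419) and Sslp1l1 at -1.21 ± 0.11 (0.0486). Both genes were as low in the EMD 82571 embryos (-0.998 and -1.13), so these calls cannot be separated from the 1 control array. The number of calls rose without RA5 or RA56, where the spread comes from the maternal liver pair alone. That pair had an SD of difference of 0.164, against 0.379 in whole embryo, so those calls do not rest on a spread of embryos. The number also rose without either retinoic acid maternal liver.

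**Figure D2:**
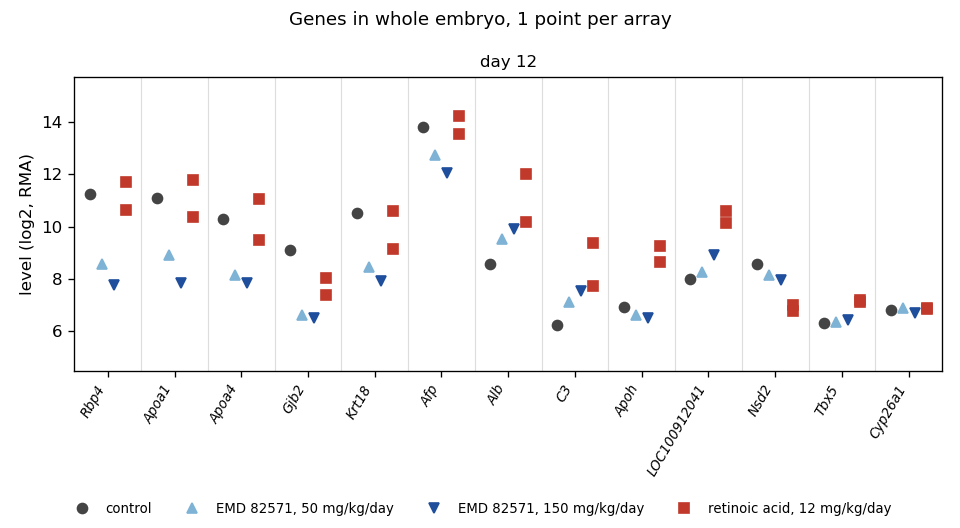
Levels of 13 genes (log2, RMA) in the whole embryos of day 12, 1 point per array. Rbp4, Apoa1, Apoa4 and Gjb2 are lower in both EMD 82571 arrays than in the control, and Alb, C3 and Apoh are highest in the retinoic acid arrays.

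In the maternal livers of day 12, EMD50 and EMD150 were above control for Cyp3a23-3a1, at 12.15 in the control, by 0.81 and 1.11, for Ugt2b1 by 0.69 and 1.30, for the bile pump gene Abcc3 by 0.59 and 1.32 and for Gsta3 by 0.75 and 1.03. The detoxification list had a median of 0.24 (percentile 100). The acinar list had a median of -1.52 (percentile 0), and Amy2a3 differed by -1.04 at the low and -6.03 at the high dose. The red cell genes Hbb (-1.25 and -1.17) and Alas2 (-1.44 and -1.66) and the fat gene Fabp4 (-2.64 and -2.51) were lower at both, while the red cell list as a whole had a median of -0.021 (percentile 18.61). Both retinoic acid arrays differed alike from this 1 control, in Hbb (-1.36 and -1.37), Fabp4 (-2.36 and -2.27) and Amy2a3 (-6.01 and -5.99). Only 10 probe sets differed by 2-fold at both doses, 9 of them lower. In the retinoic acid arrays the level of Cyp26a1 lay above the 7.29 of the control by 2.76 and 4.33, of Lrat, which stores retinol, by 1.20 and 1.03, and of the metallothionein gene Mt2A by 1.35 and 1.25. Alas2 differed by -1.76 and -2.26, the red cell list had a median of -0.16 (percentile 0) and fatty acid synthesis 0.19 (percentile 100). Both retinoic acid arrays differed from control by 2-fold in 33 probe sets, 29 of them lower.

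At day 20, both EMD 82571 doses had less Sds, which breaks down serine, by -2.47 and -2.16 from 11.50, and less of the PPAR-alpha target Acot1, by -2.15 and -2.04. They had more Pnpla3, by 1.14 and 1.24, and Scd2, by 0.80 and 2.84, of fat synthesis, a list with a median of 0.21 (percentile 100). The retinoic acid liver differed from the same 1 control alike, for Sds (-2.30), Acot1 (-2.22), Pnpla3 (1.78) and Scd2 (1.93), which a control that stands apart would also give. Amy2a3 lay at 8.42 in the control and differed by -3.16 at both doses. The retinoic acid array differed from control in 287 probe sets, 245 higher and 42 lower. The skeletal muscle genes Acta1, Myl1, Ckm and Tnnc2 were higher there by 6.25, 4.96, 3.91 and 3.79 (list median 1.04, percentile 100), to levels that no other maternal liver reached. Detoxification genes had a median of 0.39 (percentile 100), while Por, the electron donor of the cytochromes, differed by -1.55 and Nr1i2, which encodes PXR, by -1.46. Cyp26a1 differed by -0.57.

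In embryo liver of day 20, the high dose of EMD 82571 was set apart from the low dose, with 146 and 9 probe sets differing by 2-fold and 107 between the doses. PPAR-alpha genes had a median of -0.32 and gluconeogenesis genes of -0.27 (both percentile 0). Ehhadh, of peroxisomal oxidation, differed by -0.38 and -1.49, Ech1 by -0.43 and -1.25, Fbp1 by -0.27 and -1.56 and Gpt by -0.21 and -1.07. The 5 probe sets lower at both doses include the stomach genes Cym (-3.51 and -2.21) and Pga5 (-2.13 and -1.76) and Krt10, of skin (-2.03 and -1.06), which were highest in the control array. Retinoic acid had higher cholesterol synthesis genes (median 0.39, percentile 100), with Nsdhl at 1.43, Idi1 at 1.39, Msmo1 at 1.07 and Sqle at 0.93. The replication genes Prim1, Rfc4 and Rrm1 were higher by 1.54, 1.75 and 1.26, and the myeloid gene S100a8 by 1.43. Some red cell genes were higher as well, Hemgn by 0.92 and Rhag by 0.84, while Hbb differed by -0.058. Of its 157 probe sets 151 were higher, and the lower ones included Cym (-3.48) and Pga5 (-2.03).

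Embryo bone of day 20 had higher cartilage genes at both EMD 82571 doses, with Cnmd at 1.12 and 1.09, Col9a1 at 0.99 and 1.38 and the growth plate gene Col10a1 at 2.39 and 0.98 (list median 0.30, percentile 100). Col10a1 was also higher in the retinoic acid bone, by 1.39. Neurofilament genes were higher too, Nefl by 2.18 and 1.37 and Nefm by 1.76 and 1.38. The osteoclast gene Acp5 differed by -0.93 and -1.14, and muscle genes had a median of -0.24 (percentile 0), with Eno3 at -1.13 and -1.02. Liver genes were lower by far: Afp, at 12.34 in the control, by -4.52 and -4.68, Alb by -2.89 and -4.16, Fgg by -3.31 and -3.64 and Ahsg by -3.14 and -3.21. These were high in the control bone, where many other genes of embryo liver were also raised. The low dose had 559 probe sets that differed by 2-fold, the high dose 126, both 48, and the doses differed from each other in 786, with the large GAPDH 3' to 5' difference in the EMD50 array.

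Retinoic acid bone had higher bone matrix genes, with Phex, a phosphate regulator of osteocytes, at 1.99, Ogn at 1.78 and Postn at 1.20 (list median 0.26, percentile 99.88), and the hindlimb gene Pitx1 at 1.46. Some genes of other tissues were higher in this array too, such as the keratin gene Krt36 by 2.10 and the muscle genes Cox8b by 1.25 and Myog by 1.19. Neuronal genes were lower, Tubb3 by -2.55, Stmn2 by -2.50 and Rtn1 by -2.11 (list median -0.59, percentile 0). Some genes of adult liver were higher, A1bg by 3.25, Itih4 by 2.97, Cyp2c12 by 2.77 and Cyp2c7 by 2.73, while the hepatocyte list had a median of 0.14 (percentile 69.44). Of 23 genes abundant in maternal liver, 12 were higher by 0.5 or more. Alb was as high as in the control bone (13.60, difference 0.00), in which liver genes were high, and so above the EMD50 and EMD150 bones (10.70 and 9.44). Afp differed by -4.76, to 7.58, near the 7.82 and 7.66 of the EMD50 and EMD150 bones. There were 457 probe sets that differed by 2-fold, 381 higher and 76 lower.

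**Figure D3:**
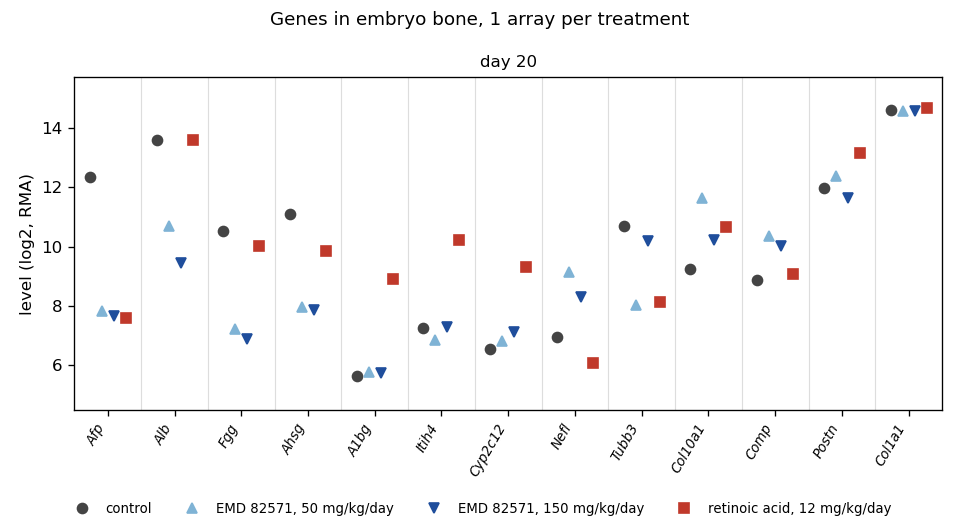
Levels of 13 genes (log2, RMA) in embryo bone of day 20, 1 array per treatment. Afp, Alb, Fgg and Ahsg are high in the control bone, Afp at 12.34, and Alb is as high in the retinoic acid bone. A1bg, Itih4 and Cyp2c12 are highest in the retinoic acid bone, while Col1a1 lies between 14.55 and 14.68 in all 4 arrays.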

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

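The tests of pancreas, fat and liver RNA and of leaving out sets of 3 retinoic acid arrays were chosen after the result was seen. For the liver RNA tests the level limits were changed once after a first look, and both versions are given. For the fat tests the bar for arguing against the source was made stricter after a first look.

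The EMD50 bone array stood out in a quality measure. The difference between the 3' and 5' probe sets of Gapdh on the array was 2.72 log2 units, above the highest control array at 0.796. No biological explanation was tested.

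Cyp26a1, which encodes the enzyme that degrades retinoic acid, was above control in the retinoic acid maternal livers of day 12 but not in that of day 20. It was higher than control by 2.76 (RA5) and 4.33 (RA56) at day 12 and differed by -0.57 (RA56) at day 20. The day 20 value is 1 array against 1 control, so it shows no effect in the other direction. The protocols give dosing up to day 11 or day 17, so the time from the last dose may also differ between the days. The difference between the days was not tested within this tissue, and over all strata it did not pass, at -1.89 ± 0.92 (day 20 minus day 12, limma, adjusted p = 0.634).

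Retinoic acid and EMD150 arrays differed in 2282 probe sets, with Maf, Lsm5 and Ggnbp2 among those higher in retinoic acid. Array spread is argued against as the whole cause, with 1877 called after quantile normalisation. With the Gapdh difference as a covariate 2545 were called. Its only large value, 2.72, is that of the EMD50 bone, which is in neither group. That fit therefore cannot decide on RNA integrity, which stays open. Separate handling of the day 20 retinoic acid arrays stays open: the 403 probe sets called higher there had medians of 0.27 and 0.56 in the day 12 embryos and 0.15 and 0.084 in the day 12 maternal livers. RNA of another tissue in 3 of the 7 retinoic acid arrays may also be a cause, with 2 called without them, but 8 of the other 34 sets of 3 gave as low a count (median 706, range 0 to 3924). An effect of the treatment stays open as untested.

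The acinar genes Amy2a3, Prss1 and Ctrb1 were high in the control maternal livers and in the EMD50 liver of day 12, and low in the other maternal livers. RNA of pancreas is a candidate source that stays open. For 15 of 21 acinar genes the log2 ratio of the excess in the controls, day 12 over day 20, had a median of 2.06 and an SD of 0.611. That SD lies between the bars set for and against 1 shared ratio. Cpa1 and Amy1 were high in all maternal livers. Fat tissue as a common source stays open too, since 5 adipocyte genes raised in the day 12 control (median 0.79) had a median of -0.098 in the day 20 control against the retinoic acid array, which carries muscle genes, and of 0.36 against the EMD 82571 arrays. In the EMD50 liver of day 12 these 5 genes had a median of 0.179 (-0.32 to 0.42) where acinar genes had 2.02, which leaves it open. An effect of the treatment stays open as untested, and the EMD50 liver of day 12 sets the pattern apart from a plain split of control and treated.

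Liver genes such as Afp and Alb were high in control bone, and Alb, A1bg and Itih4 in retinoic acid bone. Embryo liver RNA in control bone may be the source, since 15 of 16 genes abundant in embryo liver were higher there (0.938, and 0.767 in the first version) against 0.018 of 3177 genes low in embryo liver. For retinoic acid bone the median was -0.236 over 4 genes of embryo liver (first version -0.36). Only 2 of these 4 genes were higher by 0.5 or more in control bone, so so small a set cannot decide, and embryo liver RNA stays open there. Maternal liver RNA stays open for the retinoic acid bone, with 12 of 23 genes higher (0.522, first version 0.474, and 0.043 in control bone). It stays open too for the RA56 embryo, with 34 of 53 (0.642, first version 0.345, and 0.585 in RA5). A treatment effect on liver genes stays open as untested, and with 1 array per treatment in bone it cannot be told apart from such RNA.

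Treatments were regrouped 100 times within the strata, the real grouping included. For EMD150 against retinoic acid 1 of 100 gave as many calls (real 2282, highest other 605). A random split of the arrays is argued against for that count. For retinoic acid against control over all strata it was 2 of 100 (real 291, highest other 291). In the conceptus it was 4 of 100 (real 302, highest other 3162), and at day 20 3 of 100 (real 424, highest other 1613). Other groupings matched or passed these counts, so chance is not excluded for retinoic acid against control. Arrays were regrouped within each stratum on their own, so samples that share a dam or litter across strata are not covered. What sets apart the regroupings with 3162 and 1613 calls, several times the real count, was not tested. Where the real count was 0, all 100 gave as many by construction, which says nothing about chance. The highest other counts were for EMD150 against control 237, EMD50 against control 118, EMD150 against EMD50 223, EMD 82571 in the conceptus 545 and at day 20 424. For day 20 against day 12 in maternal liver, 1 of 24 regroupings of the days gave as many (real 965, highest other 8). That 1 is the real grouping, the lowest result this test can give. A random split of the arrays is argued against for that count, but chance is not excluded. Livers of a day that share a dam, handling or RNA integrity are not covered either.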

How the results depend on the processing

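Fits with quantile normalisation within a stratum, arrays scaled to the same SD, the Gapdh difference as a covariate, and without the EMD50 bone, the 3 retinoic acid arrays or the bone arrays were chosen after the data were seen, as was leaving out arrays for the lists. The cause was not tested for any change below except where fewer arrays or genes are named. Of the counts under alternatives, 797 were within 1.5 times the count reported, 157 were not, 32 fell to 0 and 55 rose from 0. No analysis paired by dam was possible because the labels name no dam or litter. The codes RA5 and RA56, which the retinoic acid arrays of different tissues share, are unexplained and absent from the other groups. As samples of the same treatment and day may share a dam, a fit took treatment and day as a random block. Its consensus correlation was -0.0155 in the first model and -0.0262 in the model by side.

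Quantile normalisation over all arrays gave 1 call for EMD 82571 in maternal liver (0 as reported), 277 for retinoic acid at day 20 (424), and in the whole embryo alone 1 for EMD 82571 (0) and 2 for retinoic acid (5). Within each stratum it gave 1, 200, 1 and 2. Arrays scaled to the same SD gave 191 for retinoic acid over all strata (291), 1 for EMD 82571 in maternal liver, 0 for retinoic acid in the whole embryo alone and 17 for EMD 82571 in maternal liver of day 12 alone (11). With each array's median subtracted, retinoic acid in the conceptus had 169 calls (302).

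With fewer probe sets after the filter on low values (9862 kept), EMD150 against retinoic acid had 1429 calls (2282), EMD 82571 in maternal liver 1, retinoic acid in maternal liver 1 (12), retinoic acid in the whole embryo alone 1, and in maternal liver of day 12 alone EMD 82571 1 and retinoic acid 6 (19). The 2-fold counts were then 20 for retinoic acid in maternal liver of day 12 (33), and for EMD 82571 9 in maternal liver of day 20 (19) and 1 in embryo liver (5). With 1 probe set per gene, EMD150 against retinoic acid had 1343 calls, retinoic acid in the conceptus 177 and in the whole embryo alone 0. Without the trend in eBayes, retinoic acid in the whole embryo alone had 0 and EMD 82571 in maternal liver of day 12 alone 1. With fewer arrays through the mean of each retinoic acid pair, retinoic acid had 0 calls in maternal liver and 147 in the conceptus, and day 20 against day 12 had 591 (965).

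With only the arrays of the groups compared, and so fewer arrays, retinoic acid had 72 calls over all strata, 0 in maternal liver, 104 in the conceptus and 229 at day 20, and EMD150 against retinoic acid 562. In the day 12 tissues alone the counts were 57 and 67 in whole embryo for EMD 82571 and retinoic acid, and 51 and 54 in maternal liver. With the Gapdh difference as a covariate, retinoic acid at day 20 had 637, day 20 against day 12 in maternal liver 20, and the day 12 tissues alone 167 and 450 in whole embryo and 54 and 56 in maternal liver. Under that covariate, which separates the days in maternal liver by itself, Nr0b2 reversed between the days, from 1.31 to -0.30.

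Without the EMD50 bone retinoic acid had 437 calls over all strata and 654 at day 20, and 1 list was called for EMD 82571 in the conceptus (3). Lists then lost were the cartilage (0.507), hepatocyte (0.635), gluconeogenesis (0.167), PPAR-alpha (0.103) and hypoxia (0.216) lists for EMD50, cartilage (0.0655) and hepatocyte (0.0874) for EMD 82571 in the conceptus, and cholesterol for retinoic acid in maternal liver (0.0619). Without the 3 retinoic acid arrays with genes of another tissue, and so with fewer arrays, retinoic acid had 0 calls over all strata (1197 probe sets at an unadjusted p under 0.05, limma), 42 in the conceptus, 20 at day 20 and 2 for conceptus minus maternal liver (0). EMD150 against retinoic acid had 2, EMD 82571 in maternal liver 1, day 20 against day 12 in maternal liver 1650, and the day 12 tissues alone 4879 and 6603 in whole embryo and 55 and 54 in maternal liver. There were 11 lists for retinoic acid in maternal liver (7), but those of cholesterol (0.59) and muscle (0.0636) were lost, as were cholesterol over all strata (0.649) and bone matrix in the conceptus (0.0514). Without the control and EMD50 bone as well, the counts were 0 for retinoic acid over all strata, 5 for EMD150 against retinoic acid, 111 in the conceptus, 124 at day 20, and 1650, 4879, 6603, 55 and 54 for the models of day 12 and maternal liver. The lists were then 18 for EMD50 (10), 15 for retinoic acid (8), 12 in maternal liver and 10 in the conceptus (6). Lists reported and lost there were the cartilage (0.817), hepatocyte (0.523) and gluconeogenesis (0.263) lists for EMD50, the nervous system list for EMD150 (0.0654), the cartilage (0.301) and hepatocyte (0.904) lists for EMD 82571 in the conceptus, and cholesterol for retinoic acid over all strata (0.39) and in maternal liver (0.618).

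With an estimated correlation, the lists called were 0 for EMD150 (6), EMD50 and retinoic acid over all strata, 4 for EMD 82571 in maternal liver (10), 0 in the conceptus, and for retinoic acid 2 in maternal liver and 0 in the conceptus. Fry called 0 lists in all of these but retinoic acid in maternal liver, with 1. With the mean of a gene's probe sets, calcium handling for EMD 82571 in the conceptus (0.0748) and cholesterol for retinoic acid in maternal liver (0.102) were lost, and no other list reported. The lists were not tested again after quantile normalisation or other rescaling of the arrays.

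At a threshold of 1.5-fold in place of 2-fold, the counts of EMD 82571 and retinoic acid were 812 (63) and 487 (62) in whole embryo, 55 (10) and 73 (33) in maternal liver of day 12, 54 (19) and 1153 (287) in maternal liver of day 20, 31 (5) and 707 (157) in embryo liver and 157 (48) and 1859 (457) in bone. At 3-fold they were 17 and 11, 2 and 20, 6 and 71, 3 and 11, and 17 and 82.

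Leaving out each array or stratum in turn kept EMD150 and EMD50 against control, EMD150 against EMD50 and EMD 82571 at day 20 at 0 calls (limma, with 2925, 253, 2311 and 677 probe sets at an unadjusted p under 0.05 in full). The other ranges were 0 to 478 for retinoic acid over all strata, 5 to 4156 for EMD150 against retinoic acid, 0 to 19 for EMD 82571 and 0 to 66 for retinoic acid in maternal liver, 0 to 7 and 1 to 452 in the conceptus, and 0 to 18 and 0 to 35 for the difference. By day they were 0 to 24 and 0 to 25 at day 12, 0 to 654 for retinoic acid at day 20, and 0 to 10 and 0 to 5 for the difference. Day 20 against day 12 ranged from 183 to 1650, and the day 12 tissues alone from 0 to 4879 and 4 to 6603 in whole embryo and from 9 to 56 and 19 to 54 in maternal liver. Without 1 array of a retinoic acid pair, the spread there comes from the pair of the other tissue alone.

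The lists called ranged from 1 to 8 for EMD150, 2 to 12 for EMD50 and 5 to 11 for retinoic acid over all strata, from 6 to 11 and 1 to 8 for EMD 82571 in maternal liver and conceptus, and from 3 to 11 and 3 to 9 for retinoic acid. The arrays that moved a count by over 1.5 times are named with each result. Of the values of single genes under alternatives, 7776 stayed on the same side of the threshold, 882 were weaker, 129 stronger and 1 reversed. Arrays give no depth, and the range of values from 4.86 upward limits what can be seen of genes near background.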

Other observations

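All that follows here was chosen after the values were seen, and no hypothesis was tested on it. Clock output genes moved together in the retinoic acid maternal liver of day 20. Dbp, a transcription factor of the clock's output, lay at 7.51 against 10.06 in the control, and it differed from control by -0.27 and -1.07 at the low and high dose of EMD 82571. Per2 differed from control by -1.86 in that retinoic acid liver, while Bmal1, which peaks at the opposite time of day, was higher by 1.02. The clock list had a median of -0.27 (percentile 0). At day 12, Dbp lay at 7.02 in the control, 7.12 and 7.35 at the doses of EMD 82571, and 8.80 (RA5) and 7.10 (RA56) with retinoic acid. The times of day of sampling are not given in the sources used here. Metallothionein gene Mt2A, which binds zinc, differed from control by -2.37 at day 20 with retinoic acid, and by -0.72 and -1.41 at the doses of EMD 82571.

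A2m, a protease inhibitor gene that rises late in rat pregnancy, was higher by 3.50 in the EMD150 maternal liver of day 12 and by 0.17 in the EMD50 one. The retinoic acid livers of that day differed by -0.08 and -0.17. In the day 20 livers it lay at 12.73 in the control and differed by -0.68 and -0.62 at the doses and by 0.34 with retinoic acid.

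Xist, made in cells with an inactive X chromosome, lay at 9.96 in control bone, 11.30 in EMD50 bone, 6.00 in EMD150 bone and 11.71 in retinoic acid bone. In embryo liver the values were 8.86, 9.63, 6.64 and 11.41 in the same order. The whole embryos lay between 9.10 and 10.88. The sex of the embryos and the number pooled are not given in the sources used here.

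Salivary gland genes appeared in embryo bone. Csap1 lay at 10.41 in control bone, 8.06 at EMD50, 9.82 at EMD150 and 6.75 with retinoic acid, and Bpifa2f was at 10.36 in control bone and differed by -2.19, -0.10 and -2.93 in the same order. In the control embryo liver the stomach genes Cym and Pga5 lay at 9.59 and 9.71, and Cym at 6.08, 7.38 and 6.11 in the EMD50, EMD150 and retinoic acid embryo livers. Amy1 was at 7.73 in the control embryo liver and at 9.34 in the retinoic acid one, and between 11.30 and 12.24 in the maternal livers.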
